A study of Mus musculus with 18 samples.

How the data were processed

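Single cells from the livers of mice were captured in droplets and sequenced from the 5' end of their transcripts with unique molecular identifiers (UMIs), per the labels. Livers were dissociated and centrifuged on a Percoll density gradient, which leaves a fraction rich in lymphocytes. The liver series held 3 libraries from wild-type mice (WT) and 3 libraries from mice homozygous for a deletion of the 8 Sult2a sulfotransferase genes (KO), each with gene expression and T cell receptor (TCR) sequences. The thymus series held 1 pooled library of thymocytes from 3 WT and 3 KO hashtags, and 1 WT library enriched by magnetic sorting with an MR1 tetramer loaded with 5-OP-RU, the bacterial metabolite antigen of mucosal-associated invariant T (MAIT) cells. Mice were 5 weeks old, per the labels, except that the labels of the tetramer library gave no age. The labels do not say that the liver libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part.

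The deposited gene tables held raw UMI counts per gene and cell barcode, made with Cell Ranger 6.0.0 on GRCm38 (mm10), per the submitters' processing notes. Which barcodes counted as cells was decided by the authors before deposit, and any further cell filter was not given in the sources used here. The deposited receptor tables held counts of cells per clonotype and the fraction of a library's cells in each clonotype, with columns for MAIT and invariant natural killer T (iNKT) evidence per chain. Hashtag counts were part of the thymus matrices. The tables named 32285 gene IDs, of which 32235 (99.8%) had a position in the annotation used here, on the same build. The Sult2a, Hba, Hbb, Klra, Trav and Ighv families have near-identical members, so reads can be split or lost between paralogs and their single-gene values are uncertain. Which Sult2a part the reads cover does not matter for this check, because the allele name gives a deletion of all 8 genes.

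Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs. In each liver library the cells with the highest Scrublet doublet scores, at an expected rate of 2.5%, were removed as doublets, which were between 2.48% and 3.65% of cells. The liver cells were clustered together with Scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, leidenalg 0.10.2 at resolution 1.5, seed 1), and the thymus libraries apart at resolution 1 and 0.5. A cluster was called X-like only from marker lists, where at least 3 markers rose by 0.5 on the log2 scale and the mean rise was at least 0.75. A cluster with leading genes of another type kept its number. The score rule was set after the data were seen. Clusters 3 and 13 in liver were T cells that stayed unnamed, with gamma delta T as the nearest list. T cells were the clusters with at least 500 CPM (UMIs scaled to a library sum of 1e6) of Cd3e, except a cycling-like cluster and cluster 25, whose nearest lists were cycling and erythroid. Cells were not treated as replicates. Counts were summed per library over all kept cells, over T cells and over each class with at least 20 cells in every library, which gave 14 sums in liver and 1 in the thymus pool.

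KO was compared with WT by edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, without covariates. Each log2 fold change is given with its standard error (SE). Levels are CPM with the SD over 3 libraries. Lists of genes were tested by camera of limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry. 32 lists were fixed, of which those with enough measured members were tested in each sum. Shares and receptor values were compared by two-sided exact permutation tests over 20 assignments of the 6 libraries, where 3 against 3 cannot give a p under 0.1. Intervals of single shares are exact Clopper-Pearson intervals at 95%, and a count of 0 is given the limit of 3 counts unless a Clopper-Pearson bound is named. Intervals and limits cover counting error only.

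The cell types, lists, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named up to 12 called genes per direction with the smallest p and no overlap between the groups, every called member of a list, the Sult2a genes, Trav1 and Trav11. It added up to 4 members of each list as examples. Where fewer than 5 genes were called, the 3 genes with the smallest p in each direction were named as not passing. Receptor and immunoglobulin segments were otherwise given as a count. A Trav1 or Trav11 T cell had at least 1 UMI of that segment. Thymus cells were assigned to a hashtag with at least 10 counts and 66.67% of the hashtag counts of the cell. Clonotypes were also counted in 720 cells drawn 1000 times from each library.

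The edgeR step was tested on simulated data with 200 genes changed by known folds. Counts were drawn at the trend of the fitted dispersion, with no further spread per gene and no structure of the samples. So many changed genes also ease the adjustment. The shares recovered may thus be higher than real data would give. In T cells the edgeR step recovered 65.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 98.5% of those changed 4-fold. Over all cells the shares were 17.9%, 40.3% and 90.9%, in iNKT-like cells 28.4%, 73.1% and 93.9%, and in monocyte-like cells 7.46%, 49.3% and 87.9%. False calls were 3 of 165 in T cells (1.82%), 5 of 104 over all cells (4.81%), 12 of 142 in iNKT-like (8.45%) and 7 of 103 in monocyte-like cells (6.80%), the last 2 above the threshold of 5%.

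The alternatives were DESeq2 1.42.0 on the same sums, its size factors within edgeR, no low-count filter, the replicate number as a block, each library left out in turn, a stricter cell filter (500 genes, 5% mitochondrial UMIs), doublets kept, a resolution of 0.75, a looser hashtag call (5 counts, 50%), and other definitions of shares and receptors. Chosen after seeing the data were sums without the interferon-led clusters 8, 24 and 26, sums without the hepatocyte, erythroid and platelet clusters, a term for a split of the libraries by Klra8, camera without each library, and NK-like cells without cells of 50 or more hemoglobin UMIs. Libraries of a group differed far beyond sampling noise, with a chi-square per gene of 19.3 to 37.6 against a simulated highest value of 1.03. This checked that no library was a second read of another, and it is no test of whether they came from separate animals.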

Results

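Gene expression and TCR sequences of single liver cells were read in 3 WT and 3 KO libraries, and those of thymocytes in 1 pooled library of both genotypes and in 1 WT library enriched with an MR1 tetramer. The comparison of interest was KO against WT. Sult2a enzymes add sulfate to bile acids and steroids, and the series title names a sulfated bile acid as an antigen that MR1 presents to MAIT cells. WT replicates 1, 2 and 3 held 9121725, 10755095 and 14098312 UMIs in 1319, 1764 and 2348 kept cells. KO replicates 1, 2 and 3 held 14518963, 12826849 and 11093537 UMIs in 2280, 2106 and 1547 kept cells. The median cell of a liver library held between 5196 and 6049 UMIs. The thymus pool held 3086995 UMIs in 321 cells, and the tetramer library 541934 UMIs in 53 cells.

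The deleted genes were read first. Sult2a transcripts were found in all 3 WT libraries and in no KO library. Over all barcodes, WT replicates 1, 2 and 3 held 62, 27 and 65 Sult2a UMIs, and each KO library held 0. In kept cells the sum was 3.93 ± 1.53 CPM in WT (SD, n = 3), at least 49.4-fold above the KO limit, which was set at 3 counts pooled over the group. Sult2a8, a liver sulfotransferase gene (ENSMUSG00000030378, GRCm38 chromosome 7, 14410686 to 14446769, minus strand), held 27, 19 and 49 UMIs in the kept WT cells and was at least 35.8-fold lower in KO. Sult2a2 held 15, 4 and 3 UMIs, Sult2a1 7, 2 and 1, and Sult2a5 1, 1 and 2, while Sult2a3, Sult2a4, Sult2a6 and Sult2a7 held 0 in every library. These genes lie between 13623967 and 14494230 on chromosome 7, and their near-identical sequences make the split between them uncertain. The exact permutation test of the Sult2a sum gave p = 0.1, the smallest it can give. By edgeR, Sult2a8 did not pass (adjusted p = 0.203, n = 3 and 3), with adjusted p between 1.41e-05 and 0.783 over its alternatives, and only DESeq2 called it.

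**Figure D1:**
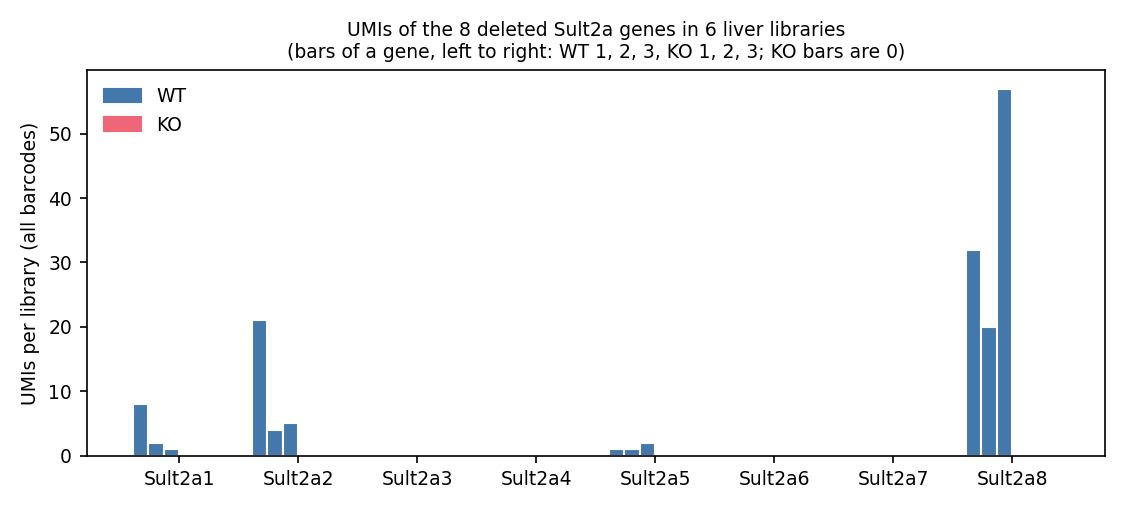
UMIs of each of the 8 Sult2a genes per liver library over all barcodes, with 6 bars per gene in the order WT replicates 1, 2 and 3 and KO replicates 1, 2 and 3. Bars are seen for Sult2a8, Sult2a2, Sult2a1 and Sult2a5 in WT, whose sums are 62, 27 and 65 UMIs, and the KO bars are at 0.

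Hepatocytes, the parenchymal cells that make Sult2a enzymes, were rare in this fraction and rarer in KO. Of the 131 Sult2a UMIs in kept WT cells, 124 lay in hepatocyte-like cells, where the sum was at least 9.09-fold lower in KO. Hepatocyte-like cells were 2.59% ± 0.22 of WT cells and 0.568% ± 0.268 of KO cells (SD, n = 3, exact permutation p = 0.1). Their median depth was 1400 UMIs. Alb, which encodes serum albumin, was at 15.3 ± 0.81 CPM in WT and 7.38 ± 4.28 CPM in KO kept cells (n = 3, exact p = 0.1). Apoa1, which encodes the main protein of high-density lipoprotein, was at 4.12 ± 0.96 and 1.14 ± 0.05 CPM (n = 3, exact p = 0.1).

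Over all liver cells, 1 gene rose in KO and none fell. Lcn2, which encodes the iron-siderophore binding protein lipocalin-2 of neutrophil granules (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 20.8 ± 2.06 to 80.9 ± 14.1 CPM (log2 1.96 ± 0.14 SE, edgeR adjusted p = 0.0387, n = 3 and 3, higher in all KO libraries). Among genes that did not pass, Ly6g, a neutrophil surface marker, was at log2 2.42 ± 0.36, Klk1b27 at 1.59 ± 0.24 and Isoc2a at 0.77 ± 0.09. In the other direction were Phyh, a peroxisomal enzyme of branched fatty acid breakdown (log2 -0.85 ± 0.08), Aldh1a1, a retinaldehyde dehydrogenase (-2.59 ± 0.29), and the apolipoprotein gene Apoc3 (-2.24 ± 0.26). Their adjusted p-values lay between 0.0844 and 0.239. At an unadjusted p under 0.05 there were 623 of 12797 genes, and DESeq2 called 83, 8 higher and 75 lower in KO. The Lcn2 call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.415, 0.315 and 0.184), without KO replicate 1 (0.324), with the replicate block (0.127) and with doublets kept (0.0552). Its adjusted p lay between 1.96e-28 (by DESeq2) and 0.415 over its alternatives, and without KO replicate 3 there were 6 calls.

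As groups, RNA of hepatocytes fell and RNA of neutrophils rose over all cells. The hepatocyte list fell (15 genes tested, median log2 -1.50, camera adjusted p = 2.22e-17, adjusted p = 0.0881 with an estimated correlation, fry adjusted p = 0.0216). No member was called over all genes, and 10 fell when adjusted over the list alone, with Apoc3, Apoc1 (-1.50 ± 0.18), Serpina3k (-1.84 ± 0.26) and Apoa1 (-1.84 ± 0.26) first. The bile acid synthesis and transport list, whose enzymes are made by hepatocytes, fell too (7 of 18 genes measured, median -0.39, adjusted p = 6.62e-05, adjusted p = 0.153 with an estimated correlation), and 2 members fell when adjusted over the list alone. Baat, which joins bile acids to taurine, was at -2.79 ± 0.39, Akr1d1, a reductase of bile acid synthesis, at -2.58 ± 0.78, and Abcb4, a phospholipid exporter of bile, at -0.96 ± 0.34. These lists moved with the lower share of hepatocyte-like cells. The neutrophil list rose (11 genes, median 0.83, adjusted p = 3.72e-07, adjusted p = 0.622 with an estimated correlation), with 4 members higher when adjusted over the list alone. Ltf, Ngp and Camp, which encode granule proteins of young neutrophils, were at 4.93 ± 0.98, 4.39 ± 0.92 and 4.69 ± 1.07. The erythroid list fell (8 genes, median -1.20, adjusted p = 2.4e-05, adjusted p = 0.632 with an estimated correlation), beside a share of hemoglobin-dominated barcodes of 36.0% ± 10.2 in WT and 16.7% ± 15.4 in KO (SD, n = 3, exact p = 0.2).

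Interferon-induced genes and naive T cell genes also rose over all cells. The interferon list (23 genes, median 0.36, camera adjusted p = 7.91e-05, adjusted p = 0.652 with an estimated correlation) held Oasl1 at 0.93 ± 0.29 and Gbp2 at 0.42 ± 0.15, and its call was lost without KO replicate 1 (0.0792). The naive T list rose (10 genes, median 0.30, adjusted p = 0.000121, adjusted p = 0.632 with an estimated correlation), with the transcription factor gene Tcf7 at 0.32 ± 0.09. Class II antigen presentation genes rose (median 0.34, adjusted p = 0.00166, adjusted p = 0.652 with an estimated correlation) and cytotoxic genes fell (median -0.25, adjusted p = 0.00383, adjusted p = 0.632 with an estimated correlation). Both calls were lost without WT replicate 2 (0.228 and 0.228) and without KO replicate 2 (0.106 and 0.0667). The cytotoxic list holds Klra8 and Klra4. In NK-like cells Klra8 was at 367, 0 and 315 CPM in WT replicates 1, 2 and 3 and 0, 0 and 264 CPM in KO. Klra4 ran likewise, while Gzma and Eomes, also listed, did not. Whether such members carried the fall was not tested. Beside the naive T, class II and cytotoxic lists, B-like cells were 11.3% of WT and 13.5% of KO cells (n = 3, exact p = 0.4), pDC-like cells 1.83% and 2.90% (exact p = 0.3), conventional CD4 T-like cells 12.5% and 16.7% and effector or memory CD8 T-like cells 2.77% and 1.10% (both exact p = 0.2). Cycling genes fell (median -0.09, adjusted p = 0.0111, adjusted p = 0.657 with an estimated correlation), a call lost without WT replicate 1 or 3 (0.111 and 0.0696) or KO replicate 1 (0.154) and turned in direction without KO replicate 2 (0.992). Thymic export genes rose (median 0.24, adjusted p = 0.0206, adjusted p = 0.651 with an estimated correlation), a call lost without WT replicate 2 (0.156) or KO replicate 2 (0.270), and so did thymic MAIT stage 1 genes (median 0.15, adjusted p = 0.0392, adjusted p = 0.632 with an estimated correlation). The stage 1 call was lost without WT replicate 1 or 3 (0.103 and 0.105) and without KO replicate 1 or 2 (0.154 and 0.173). The other 19 lists tested over all cells did not pass, with adjusted p = 0.910 for MAIT cell markers, 0.223 for the type 17 program, 0.112 for the type 1 program and 0.210 for MR1 and class Ib presentation.

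Over all T cells no gene was called between KO and WT by edgeR (0 of 10711 genes, 537 at an unadjusted p under 0.05), while DESeq2 called 7. T cells were 57.7% ± 2.07 of WT cells and 58.9% ± 1.80 of KO cells (SD, n = 3, exact p = 0.6). The genes with the smallest p were Isoc2a (from 13.96 ± 0.75 to 27.5 ± 2.09 CPM, adjusted p = 0.0709), Tmem176b, a membrane channel gene of type 17 lymphocytes (0.96 ± 0.15, 0.547), and the kinase gene Lrrk1 (0.68 ± 0.12, 0.556). In the other direction were Snrpn (-1.17 ± 0.24), Gramd1a (-0.46 ± 0.09) and Tmem140 (-0.79 ± 0.17). Trav1, the variable segment of the MAIT alpha chain, was at 0.81 ± 0.52 (adjusted p = 0.922). Of the 24 lists tested, 11 passed camera and 0 passed with an estimated correlation. Naive T genes rose (median 0.30, adjusted p = 0.000984, adjusted p = 0.486 with an estimated correlation), with Tcf7 at 0.40 ± 0.11 and the lymph node homing receptor gene Ccr7 at 0.42 ± 0.20. Cytotoxic genes fell (median -0.15, adjusted p = 0.00645, adjusted p = 0.486 with an estimated correlation), with Gzma, a granzyme gene, at -0.60 ± 0.16 and Klrg1, a receptor of terminal effector cells, at -1.37 ± 0.45, and 1 member fell when adjusted over the list alone. Beside these lists, conventional CD4 T-like cells were 12.5% of WT and 16.7% of KO cells and effector or memory CD8 T-like cells, led by Gzmk, Ccl5 and Cd8a, 2.77% and 1.10% (n = 3, both exact p = 0.2). Interferon genes rose (median 0.24, adjusted p = 0.00728, adjusted p = 0.698 with an estimated correlation), with Gbp2 at 0.41 ± 0.12. Dissociation and heat shock genes fell (median -0.20, adjusted p = 0.00630, adjusted p = 0.486 with an estimated correlation). The erythroid list, which T cells do not express, fell in T cells as well (median -1.24, adjusted p = 0.000263, adjusted p = 0.486 with an estimated correlation, 4 lower when adjusted over the list alone). Of the hemoglobin UMIs, 92.0% to 97.5% per library lay in 3 to 20 T cells. In the other T cells hemoglobin was at 69.6, 83.1 and 59.3 CPM in WT and 17.9, 7.83 and 59.5 CPM in KO, which overlap.

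Smaller list calls in T cells were higher thymic export (median 0.24, adjusted p = 0.0112) and regulatory T genes (0.14, 0.0227), and lower cholesterol synthesis (-0.12, 0.0112), cycling (-0.19, 0.0227), thymic MAIT stage 3 type 1 (-0.17, 0.0131) and type 1 program genes (-0.08, 0.0367). With an estimated correlation their adjusted p-values were 0.5, 0.486, 0.486, 0.486, 0.563 and 0.607. Klrb1c, on the type 1 list, was at 63.9, 4.52 and 79.5 CPM in WT replicates 1, 2 and 3 and 5.21, 4.26 and 92.3 CPM in KO. MAIT cell markers (adjusted p = 0.932), the type 17 program (0.844) and thymic MAIT stage 3 type 17 genes (0.932) did not pass, with 2 members of each higher when adjusted over the list alone, Tmem176a and Tmem176b. Without WT replicate 2, the cytotoxic (0.148), heat shock (0.114), cholesterol (0.170), cycling (0.167), export (0.239), stage 3 type 1 (0.427) and type 1 program (0.667) calls were lost. Without KO replicate 2, the naive T (0.0529), cholesterol (0.257), cycling (0.124), export (0.250), stage 3 type 1 (0.722) and type 1 program (0.805) calls were lost, and without KO replicate 1 the interferon (0.729), heat shock (0.0722) and regulatory T (0.0504) calls. The interferon call was also lost without KO replicate 3 (0.269), the cycling call without WT replicate 1 (0.0532), and the regulatory T call without WT replicates 1 and 3, each in turn (0.0716 and 0.158).

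In iNKT-like cells, T cells that see lipids on CD1d, 1 gene rose and none fell. Emp3, a membrane protein gene (chromosome 7), rose from 75.6 ± 4.59 to 160.4 ± 23.1 CPM (log2 1.05 ± 0.13, edgeR adjusted p = 0.0138, n = 3 and 3). Emp3 was also the only gene called in cluster 3, T cells led by Trdc, Klra5, Gzmb and Cd7, where it rose from 154 ± 4.13 to 261 ± 15.3 CPM (log2 0.78 ± 0.11, adjusted p = 0.0444). In iNKT-like cells Lrrk1 (0.94 ± 0.14, adjusted p = 0.0636), Tmem176a (1.54 ± 0.26) and Tmem176b (1.52 ± 0.25) were higher without passing, and S100a4, a calcium-binding protein gene (-0.85 ± 0.14), Ctla2a (-0.61 ± 0.10) and Trat1 (-1.07 ± 0.20) lower, with adjusted p-values of 0.0703 to 0.124 after Lrrk1. Among 20 lists, erythroid genes fell (median -2.32, adjusted p = 4.2e-11, adjusted p = 0.435 with an estimated correlation, 5 lower when adjusted over the list alone). A few cells carried the hemoglobin, with 93.8%, 94.7% and 97.3% of its UMIs in 1, 5 and 6 cells of WT replicates 1, 2 and 3. In the other iNKT-like cells it was at 62.3, 108 and 42.4 CPM in WT and 24.6, 7.35 and 74.1 CPM in KO, which overlap. Heat shock genes fell (-0.28, adjusted p = 0.00430, adjusted p = 0.504 with an estimated correlation), lost without WT replicate 2 (0.302) or KO replicate 1 (0.109). Interferon genes rose (0.13, adjusted p = 0.0496, adjusted p = 0.726 with an estimated correlation), lost without WT replicate 1 or 3 (0.519 and 0.747) or KO replicate 1 or 3 (0.847 and 0.127). The Emp3 call was lost in iNKT-like cells without WT replicate 1 (0.171), KO replicate 1 (0.0681) or KO replicate 2 (0.0836). Its adjusted p lay between 2.08e-11 (edgeR without the low-count filter) and 0.171 over the alternatives. DESeq2 called 11 genes, and without KO replicate 3 there were 13 calls, against 2 without WT replicate 2 or 3.

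In cluster 3 the Emp3 call was lost without WT replicate 1, 2 or 3 (adjusted p = 0.324, 0.0921 and 0.193). It was also lost without KO replicate 1 or 3 (0.149 and 0.131) and with the replicate block (0.155). Emp3 was not called there with the Klra8 split as a term either (edgeR adjusted p = 0.0705). Its adjusted p lay between 8.83e-06 (edgeR without the low-count filter) and 0.324 over the alternatives. EdgeR called 5 genes without KO replicate 2, and DESeq2 called 2 genes. Lrrk1 (log2 0.66 ± 0.11) and the early response gene Jun (-0.64 ± 0.11) did not pass there (both adjusted p = 0.101).

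In cluster 13, T cells led by Trbv19, Ikzf2 and Ly6c2, S100a4 fell from 249 ± 74.3 to 89.3 ± 25.8 CPM (log2 -1.43 ± 0.25, edgeR adjusted p = 0.0295, n = 3 and 3) and no gene rose. Genes of killing and of the type 1 program rose as groups there. The type 1 list (15 genes, median 0.35, adjusted p = 1.37e-07, adjusted p = 0.134 with an estimated correlation) and the cytotoxic list (9 genes, 0.35, adjusted p = 2.15e-06, adjusted p = 0.0888 with an estimated correlation) each had 4 members higher when adjusted over the list alone. They share Nkg7 (0.49 ± 0.12), the granzyme gene Gzmb (1.28 ± 0.33), the chemokine gene Ccl5 (0.35 ± 0.12) and Fasl (0.66 ± 0.23), none called over all genes. Thymic MAIT stage 3 type 1 genes, most of which are also in the type 1 list, rose too (0.27, adjusted p = 0.000506, adjusted p = 0.134 with an estimated correlation). Interferon (0.28, adjusted p = 0.00914) and MR1 and class Ib presentation genes (0.23, 0.0147) rose and mitochondrial genes fell (-0.17, 0.0191), with adjusted p = 0.368, 0.293 and 0.293 with an estimated correlation. The S100a4 call was lost without WT replicate 1 or 2 (0.0731 and 0.115), KO replicate 1 or 2 (0.133 and 0.139), with the replicate block (0.0601) and by DESeq2 (0.431), the highest over its alternatives. Its lowest was 2.51e-06, by edgeR without the low-count filter. There were 4, 17 and 3 calls without WT replicate 2, WT replicate 3 and KO replicate 3. The interferon call was lost without WT replicate 2 (0.133), KO replicate 1 (0.0540) or KO replicate 3 (0.362), the MR1 call without WT replicate 2 (0.380) or KO replicate 3 (0.187), and the mitochondrial call without WT replicate 2 or 3 (0.0740 and 0.0724) or KO replicate 1 or 2 (0.114 and 0.0784).

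Conventional CD4, conventional CD8 and regulatory T-like cells had no called gene by edgeR, with 400, 364 and 229 genes at an unadjusted p under 0.05 and 0 calls each by DESeq2. In CD4 T-like cells, Gbp2 was at log2 0.78 ± 0.16 (adjusted p = 0.777) and Mlycd, a malonyl-CoA decarboxylase gene, at -1.28 ± 0.20 (0.0812). In CD8 T-like cells Nkg7 was at 0.42 ± 0.09 and Gramd1a at -0.46 ± 0.11 (both adjusted p = 0.634), and in regulatory T-like cells the interferon-induced sensor gene Zbp1 was at 0.87 ± 0.23 (0.976). Of 15 lists in CD4 T-like cells, 7 passed. Heat shock genes (median -0.22, adjusted p = 0.00586, 1 higher and 6 lower when adjusted over the list alone) and cholesterol synthesis genes (-0.18) fell. Interferon (0.24), MR1 and class Ib presentation (0.17, with the peptide transporter gene Tap1 at 0.40 ± 0.11), T cell receptor response (0.17), stage 1 (0.16) and naive T genes (0.06) rose, at adjusted p = 0.00991 for all but the naive T list (0.0496). With an estimated correlation the adjusted p-values were 0.399 for heat shock, 0.601 for interferon and 0.308 for the other 5. Without WT replicate 1 the heat shock (0.112) and naive T (0.319) calls were lost, and without WT replicate 2 the heat shock, interferon, MR1 and naive T calls (each 0.0813). Without WT replicate 3 the interferon, MR1 and stage 1 calls (each 0.0969), the cholesterol call (0.141) and the receptor response call (0.431) were lost. Without KO replicate 1 the heat shock and stage 1 (both 0.0779), interferon (0.839), MR1 (0.153) and naive T (0.300) calls were lost, without KO replicate 2 the receptor response (0.111) and naive T (0.313) calls, and without KO replicate 3 the interferon (0.144) and cholesterol (0.0793) calls. In regulatory T-like cells the interferon list alone of 18 rose (0.38, adjusted p = 0.000913, adjusted p = 0.906 with an estimated correlation, 3 higher when adjusted over the list alone), lost without KO replicate 1 (0.0827). No list of 19 passed in CD8 T-like cells. There were 4 called genes in CD4 T-like cells without WT replicate 2 and 4 without KO replicate 3, 2 in CD8 T-like cells without WT replicate 2, and 1 in regulatory T-like cells without KO replicate 2.

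NK-like cells, innate killer lymphocytes, had 3 called genes, all lower in KO and all genes of red blood cells. The beta-globin genes Hbb-bt (log2 -3.52 ± 0.55, edgeR adjusted p = 0.0176) and Hbb-bs (-3.60 ± 0.63, 0.0367) and Alas2, the heme synthesis enzyme gene of erythroid cells (-3.33 ± 0.60, 0.0367), fell (n = 3 and 3). Reads of the globin genes can be shared between near-identical copies. NK cells do not make hemoglobin, and 98.6% of the 17619 hemoglobin UMIs of NK-like cells lay in 10 of 714 cells. Genes that did not pass were Klra1, an NK receptor gene (1.24 ± 0.29), Socs3, a cytokine signal inhibitor gene (0.93 ± 0.22), Ifng (0.58 ± 0.15), the chemokine gene Ccl9 (-2.29 ± 0.43, adjusted p = 0.0554) and Ehd3 (-1.84 ± 0.40). The erythroid list fell (6 genes, median -3.28, adjusted p = 6.14e-18, adjusted p = 0.152 with an estimated correlation, 6 lower when adjusted over the list alone). The interferon list rose (0.36, adjusted p = 0.000287, adjusted p = 0.152 with an estimated correlation), lost without WT replicate 3 (0.307). Hbb-bt was not called without WT replicate 1 (0.194) or KO replicate 3 (0.101), Hbb-bs without WT replicate 1 or 2 (0.199 and 0.0956) or KO replicate 3 (0.183), and Alas2 without any single library but WT replicate 3 (0.199, 0.198, 0.0937, 0.146 and 0.101 without WT replicates 1 and 2 and KO replicates 1, 2 and 3) or with doublets kept (0.0567). The folds of Hbb-bt, Hbb-bs and Alas2 were at log2 -6.30, -4.62 and -4.20 without KO replicate 1, those of Hbb-bt and Hbb-bs at -2.83 and -2.95 without WT replicate 1, and that of Alas2 at -2.73 without KO replicate 2. Over the alternatives adjusted p-values reached 0.9998 for all 3 genes, by DESeq2. The lowest for Hbb-bt, Hbb-bs and Alas2 were 1.25e-84, 6.25e-186 and 4.11e-14, all by edgeR without the low-count filter. There the SE of Hbb-bs was 0.12 against 0.63, though KO replicates 1, 2 and 3 were at 722, 4.56 and 405 CPM. Among the other settings the lowest edgeR adjusted p of Hbb-bs was 0.00111, without KO replicate 2. DESeq2 called 0, and there were 10 calls without WT replicate 3 and 5 without KO replicate 1.

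ILC1-like cells, tissue-resident innate lymphocytes, had no called gene by edgeR (0 of 5090, 296 at an unadjusted p under 0.05) and none by DESeq2. Lrrk1 was at 1.14 ± 0.20 (adjusted p = 0.142), Myc at 0.97 ± 0.23 (0.415), and the early response genes Fos and Fosb at -0.62 ± 0.13 and -0.91 ± 0.20 (0.347 and 0.390). Genes of the dissociation and heat shock list fell together (15 genes, median -0.62, adjusted p = 3.22e-11, adjusted p = 0.0876 with an estimated correlation, 8 lower when adjusted over the list alone), with Jun at -0.73 ± 0.17 and the chaperone gene Hsph1 at -1.28 ± 0.30. Such genes respond to tissue handling as well as to signals. The interferon list rose (0.40, adjusted p = 7.04e-05, adjusted p = 0.639 with an estimated correlation), lost without KO replicate 1 (0.216). In cluster 3 the heat shock list fell likewise (17 genes, -0.41, adjusted p = 5.71e-06, adjusted p = 0.356 with an estimated correlation, 4 lower when adjusted over the list alone), with Jun at -0.64 ± 0.11. The exhaustion list fell there as well (-0.31, adjusted p = 0.0326, adjusted p = 0.356 with an estimated correlation), lost without WT replicate 2 (0.406) or KO replicate 3 (0.125). In ILC1-like cells there were 2, 6 and 5 calls without WT replicate 2, WT replicate 3 and KO replicate 3.

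In B-like cells 1 immunoglobulin segment, Ighv1-7, rose (log2 4.10 ± 0.34, edgeR adjusted p = 0.00179, n = 3 and 3), and no other gene passed. Myc, a growth regulator gene, was at 0.65 ± 0.12 and the early response gene Egr1 at -0.62 ± 0.11 (both adjusted p = 0.247). The interferon list rose (18 genes, median 0.66, adjusted p = 0.000635, adjusted p = 0.594 with an estimated correlation), with Gbp2 at 1.43 ± 0.34, Ifi27l2a at 0.95 ± 0.24 and Rtp4 at 1.58 ± 0.46 higher when adjusted over the list alone. MR1 and class Ib presentation genes rose (0.17, adjusted p = 0.0125, adjusted p = 0.530 with an estimated correlation), with H2-T23 at 0.35 ± 0.10 and B2m, the shared light chain, at 0.20 ± 0.08. Class II genes rose (0.11, camera adjusted p = 0.0125, adjusted p = 0.530 with an estimated correlation), with H2-Aa at 0.21 ± 0.06. T cell receptor response genes, here Myc and Nr4a1, rose too (0.19, camera adjusted p = 0.0125, adjusted p = 0.426 with an estimated correlation). Egr1, also on that list, went the other way (log2 -0.62 ± 0.11). The erythroid list fell (-1.54, adjusted p = 4.36e-09, adjusted p = 0.426 with an estimated correlation). A few cells carried the hemoglobin, with 98.6%, 98.08% and 99.01% of its UMIs in 4, 4 and 10 cells of WT replicates 1, 2 and 3. In the other B-like cells it was at 90.2, 267.3 and 103.9 CPM in WT and 52.8, 13.98 and 90.6 CPM in KO, which overlap. Without KO replicate 3 the interferon (0.0704), MR1 (0.102) and class II (0.102) calls were lost, without WT replicate 3 the MR1 (0.159) and class II (0.298) calls, without WT replicate 2 and KO replicate 2 the class II (0.0558 and 0.108) and receptor response calls (0.0653 and 0.0628), and without WT replicate 1 the receptor response call (0.0617). Ighv1-7 was at log2 4.81 without WT replicate 3 and at 2.96 at the lower cluster resolution, where its call was lost (edgeR adjusted p = 0.491). That was the highest adjusted p of its alternatives, the lowest being 1.12e-31 by edgeR without the low-count filter. DESeq2 called 5 genes, and 2, 3, 2, 3 and 4 genes were called without WT replicates 1, 2 and 3 and KO replicates 1 and 2.

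Myeloid cells had no called gene by edgeR without covariates. Monocyte-like, neutrophil-like and pDC-like (plasmacytoid dendritic) cells had 328, 135 and 247 genes at an unadjusted p under 0.05, and DESeq2 called 3, 14 and 0. In monocyte-like cells the neutrophil attractant gene Cxcl2 was at 1.78 ± 0.24 (adjusted p = 0.0546), and Cxcl9, an interferon-gamma induced chemokine gene, at 2.86 ± 0.47 (0.155), which was at -0.08 with doublets kept. Nkg7 (7.76 ± 1.31), Ccl5 (5.08 ± 0.99) and Il2rb (4.33 ± 0.88), markers of T and NK cells, were also higher there without passing (0.211 to 0.230). In neutrophil-like cells Chil3, a chitinase-like protein gene, was at 5.77 ± 0.82 (0.0886), and Ly6g at 2.34 ± 0.43 and Lcn2 at 1.93 ± 0.36 (both 0.246). In pDC-like cells Ly6a was at 1.45 ± 0.26 (0.176) and Hsp90aa1 at -0.74 ± 0.18 (0.832). With the replicate block edgeR called 3 genes in monocyte-like, 15 in neutrophil-like and 1 in pDC-like cells. With the Klra8 split as a term it called 9 in neutrophil-like cells. There were 3 and 4 calls in monocyte-like cells without KO replicates 1 and 3, 2, 8 and 1 in neutrophil-like cells without WT replicate 3 and KO replicates 2 and 3, and 4 and 1 in pDC-like cells without WT replicates 1 and 3.

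Neutrophil genes rose as a group in neutrophil-like cells (11 genes, median 0.61, adjusted p = 0.000356, adjusted p = 0.513 with an estimated correlation, 5 higher when adjusted over the list alone) and heat shock genes fell (-0.36, adjusted p = 5.37e-05, adjusted p = 0.513 with an estimated correlation). Mitochondrial genes fell (-0.44, adjusted p = 0.00889) and interferon genes rose (0.70, 0.0199), both at adjusted p = 0.674 with an estimated correlation. The mitochondrial call was lost without KO replicate 2 or 3 (0.129 and 0.113) and turned without WT replicate 1 (0.794), and the interferon call was lost without WT replicate 1 or 3 (0.0554 and 0.501) and turned without KO replicate 1 (0.555). In pDC-like cells interferon genes rose (0.47, adjusted p = 7.95e-05), as did MR1 and class Ib presentation (0.15, 0.00205) and class II genes (0.22, 0.0259), while heat shock genes fell (-0.35, 0.000112). All 4 were at adjusted p = 0.494 with an estimated correlation. The heat shock call was lost without KO replicate 3 (0.490), the MR1 call without WT replicate 3 (0.339), and the class II call without WT replicate 2 (0.563), KO replicate 2 (0.0631) or KO replicate 3 (0.129). In monocyte-like cells inflammatory genes rose (0.56, adjusted p = 0.0178, adjusted p = 0.460 with an estimated correlation), with Ptgs2 at 1.76 ± 0.45 and Ccl2 at -0.82 ± 0.18, lost without WT replicate 1 or 2 (0.127 and 0.0717) or KO replicate 2 (0.312). The type 1 (4.33, adjusted p = 4.2e-07), stage 3 type 1 (4.33, 8.7e-05) and naive T lists (1.27, 0.00368), which are lymphocyte genes, rose as well, at adjusted p = 0.345, 0.345 and 0.485 with an estimated correlation. Mitochondrial (0.21, adjusted p = 0.00104), MR1 (0.13, 0.0178) and receptor response genes (0.40, 0.0256) rose at adjusted p = 0.485, 0.485 and 0.345 with an estimated correlation. The mitochondrial call was lost without WT replicate 1 (0.278) or KO replicate 1 (0.0741), the MR1 call without WT replicate 1 or 3 (0.0807 and 0.106) or KO replicate 1 (0.349), and the receptor response call without WT replicate 1 or 2 (0.113 and 0.0934) or KO replicate 1 or 2 (0.143 and 0.0584).

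**Figure D2:**
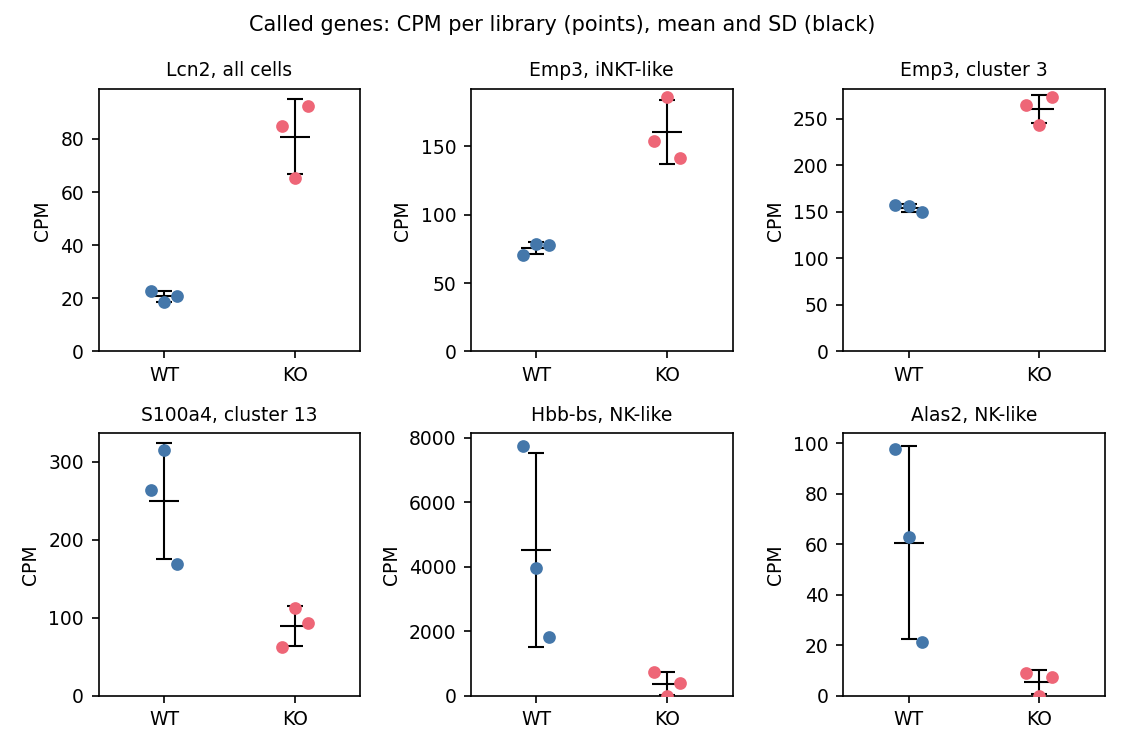
CPM per library (points) with the mean and SD (black) in WT and KO for Lcn2 over all cells, Emp3 in iNKT-like cells and cluster 3, S100a4 in cluster 13, and Hbb-bs and Alas2 in NK-like cells. Lcn2 lies at a mean of 20.8 CPM in WT and 80.9 CPM in KO.

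The classes of the lymphocyte fraction varied widely between libraries of a genotype. The exact permutation test, whose p cannot fall under 0.1 with 3 libraries per group, could pass none of the 25 classes (all adjusted p = 1) and says nothing on whether they were alike. B-like cells were 11.3% ± 3.32 in WT and 13.5% ± 1.59 in KO (SD, n = 3, exact p = 0.4), iNKT-like cells 15.1% ± 0.72 and 13.5% ± 6.59 (exact p = 0.7), conventional CD4 T-like cells 12.5% ± 2.37 and 16.7% ± 3.08 (exact p = 0.2), and NK-like cells 6.40% ± 1.54 and 5.81% ± 0.84 (exact p = 0.6). Effector or memory CD8 T-like cells were 2.77% ± 1.40 and 1.10% ± 0.56 (exact p = 0.2), and cluster 5, T cells that stayed unnamed, 2.12% ± 2.03 and 0.669% ± 0.112 (exact p = 0.4). MAIT or type 17 innate-like T-like cells were 0.292% ± 0.123 and 0.358% ± 0.220 (exact p = 0.7). They were 2, 6 and 9 kept cells in WT replicates 1, 2 and 3 and 8, 3 and 9 in KO. In the order B-like, iNKT-like, CD4, NK-like, effector or memory CD8, cluster 5 and MAIT or type 17, the differences, KO minus WT, were 2.15, -1.54, 4.23, -0.595, -1.67, -1.45 and 0.0667 percentage points. Single libraries moved them by over 1.5 times, to 3.64 (B-like), -1.45 (NK-like) and -0.00335 (MAIT or type 17) without WT replicate 1, to 0.362 (B-like), -0.396 (NK-like), -1.07 (effector or memory CD8) and -0.419 (cluster 5) without WT replicate 2, and to 0.0574 (NK-like), -2.45 (cluster 5) and 0.112 (MAIT or type 17) without WT replicate 3. They moved to -0.980 (NK-like) without KO replicate 1, to 1.25 (B-like), 1.86 (iNKT-like), 2.55 (CD4) and 0.175 (MAIT or type 17) without KO replicate 2, and to -4.73 (iNKT-like), -0.147 (NK-like) and -0.0450 (MAIT or type 17) without KO replicate 3. By edgeR on the cell counts, 1 class passed, the hepatocyte-like cells, which fell (log2 -2.15 ± 0.47, adjusted p = 0.0156).

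**Figure D3:**
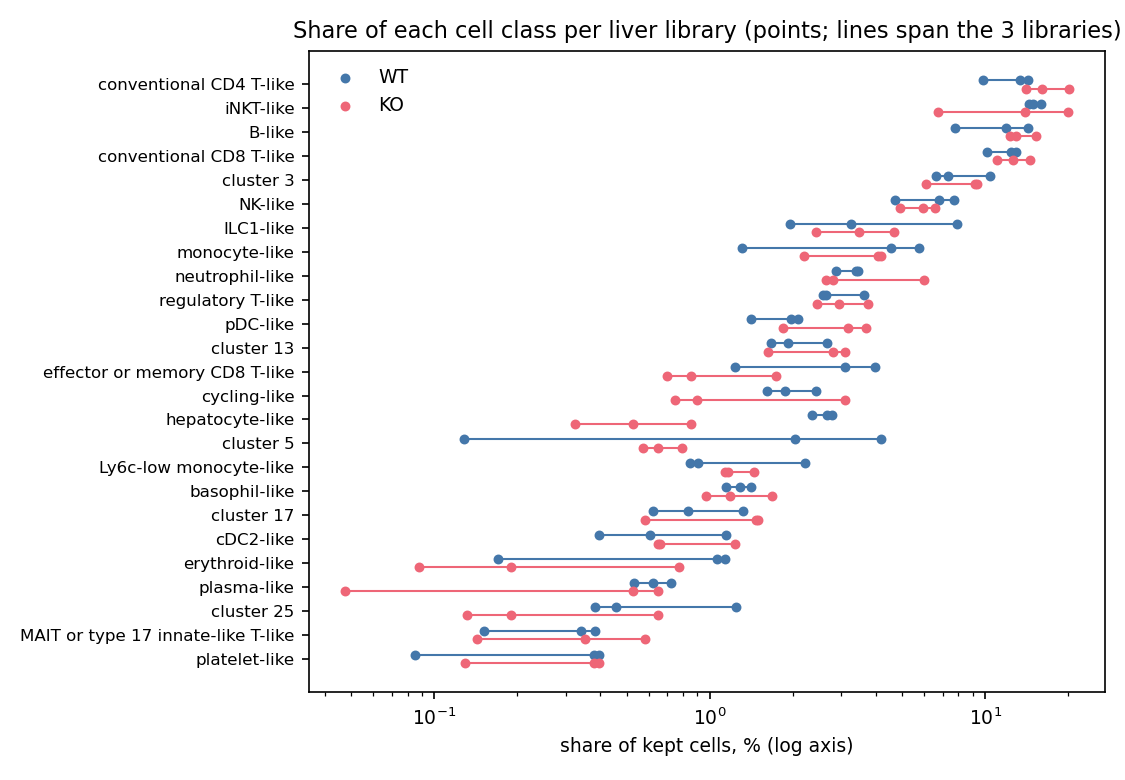
Share of kept liver cells in each of 25 classes, in percent on a log axis, with a point per library and a line that spans the 3 libraries of a group. Hepatocyte-like cells lie at a mean of 2.59% in WT and 0.568% in KO, with no overlap.

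MAIT cells were sought by their receptor. T cells with a Trav1 UMI, which are enriched for MAIT cells, were 1.41% ± 0.89 of T cells in WT and 1.94% ± 0.28 in KO (SD, n = 3, exact p = 0.6). WT replicate 1 stood lowest with 3 of 754 T cells (0.398%, interval 0.0821 to 1.16%). WT replicates 2 and 3 held 22 of 1059 (2.08%, 1.31 to 3.13%) and 23 of 1315 (1.75%, 1.11 to 2.61%), and KO replicates 1, 2 and 3 held 30 of 1373 (2.19%, 1.48 to 3.10%), 24 of 1197 (2.01%, 1.29 to 2.97%) and 15 of 922 (1.63%, 0.913 to 2.67%). B-like cells, which lack the segment, had 0 of 1412 cells with a Trav1 UMI (Clopper-Pearson upper bound 0.261%) at a median depth of 3945.5 UMIs against 5942.5 UMIs in T cells. At a depth of 2000 UMIs per cell the shares were 0.810% ± 0.475 and 1.20% ± 0.459 (exact p = 0.5). The 117 Trav1 T cells lay in the CD4 (39), iNKT-like (31), CD8 (17), MAIT or type 17 (6), effector or memory CD8 (6) and regulatory T-like (5) classes and in clusters 3 (6), 13 (5) and 5 (2). Without WT replicate 1 the difference, KO minus WT, was 0.0257 percentage points in place of 0.531, and without WT replicate 2 it was 0.866. Trav11 T cells, which carry the iNKT segment, were 3.83% ± 0.20 and 3.77% ± 1.72 (exact p = 1), and 221 of 248 lay in the iNKT-like class. The difference was 0.0517 without WT replicate 2, 0.863 without KO replicate 2 and -0.833 without KO replicate 3, and -0.122, -0.115 and -0.215 without WT replicates 1 and 3 and KO replicate 1, against -0.0618 with all libraries.

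MAIT receptors were rare in the TCR libraries of both genotypes. Cells in clonotypes with MAIT evidence on both chains numbered 0 of 720, 1 of 949 and 3 of 1230 in WT replicates 1, 2 and 3, and 1 of 1254, 1 of 1034 and 1 of 881 in KO, or 0.116% ± 0.122 and 0.0967% ± 0.0169 (SD, n = 3, exact p = 0.8). The count of 0 allows a share of up to 0.417%. The public MAIT alpha CDR3 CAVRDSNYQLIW was found in all 6 libraries. With evidence on the alpha chain alone the shares were 0.268% ± 0.143 and 0.337% ± 0.143 (exact p = 0.6). These shares of cells with a receptor lay below the Trav1 shares of T cells (1.41% and 1.94%), so a Trav1 share is not a MAIT share here. On both chains the difference was 0.0440 without WT replicate 3, -0.0780 without WT replicate 1 and -0.0113 without KO replicate 1, against -0.0198 with all libraries. Cells with iNKT evidence on both chains were 7.40% ± 0.35 in WT and 5.76% ± 2.86 in KO (exact p = 0.4), with 2.90% in KO replicate 2, without which the difference was -0.213 in place of -1.64, and -3.08 without KO replicate 3. With iNKT evidence on the alpha chain alone the shares were higher, at 25.6% ± 0.987 in WT and 20.1% ± 8.79 in KO (exact p = 0.4). KO replicate 2 was again the lowest, at 10.25%. Clonotypes numbered 917 ± 263 in WT and 1028 ± 186 in KO (exact p = 0.6), a difference of 111.7 that was -3.67 without WT replicate 1, 255 without WT replicate 3, 13.8 without KO replicate 1 and 198 without KO replicate 3. In 720 drawn cells they numbered 685 ± 23.2 and 705.5 ± 3.70 (exact p = 0.3), a difference of 20.5 that was 8.66 without WT replicate 2 and 31.9 without WT replicate 3. The 10 largest clonotypes held 5.13% ± 2.18 of WT cells and 2.52% ± 0.57 of KO cells (exact p = 0.2, -1.64 without WT replicate 2 against -2.61).

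**Figure D4:**
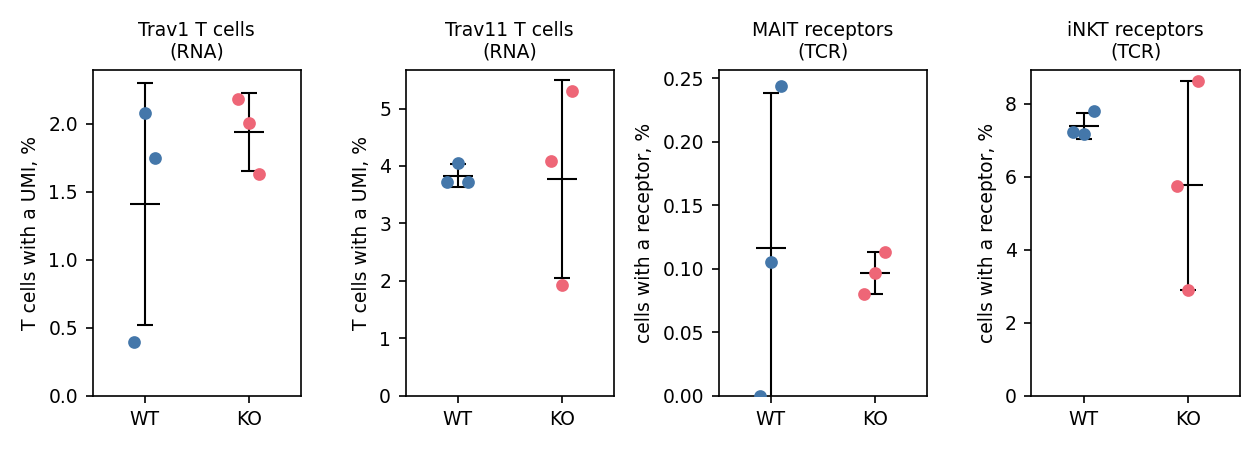
Shares in percent per liver library (points) with the mean and SD (black) for T cells with a Trav1 or Trav11 UMI and for cells with MAIT or iNKT receptors in the TCR libraries. The Trav1 share of WT replicate 1 lies at 0.398%, and the other libraries lie between 1.63% and 2.19%.

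In the thymus pool, all 321 cells carried a hashtag, but 25 cells were WT and 296 KO. WT hashtags 2, 3 and 7 held 7, 9 and 9 cells and KO hashtags 4, 5 and 6 held 174, 4 and 118, so the comparison rests on few WT cells. Cells with a Trav1 UMI were 18.5% ± 32.1 of WT and 14.2% ± 14.1 of KO cells (SD, n = 3, exact p = 1). KO hashtag 4 held 49 (28.2%, interval 21.6 to 35.5%), KO hashtag 6 held 17 (14.4%, 8.62 to 22.1%) and WT hashtag 7 held 5 (55.6%, 21.2 to 86.3%). WT hashtags 2 and 3 and KO hashtag 5 held 0, which allows up to 42.9%, 33.3% and 75% of their cells. Trav1 cells made up 19 of 24 type 17-like cells (79.2%), a cluster led by Lgals3, Tmem176a and Blk, and 13 of 19 type 1-like cells (68.4%), led by Ccl5, Gzma and Nkg7, against 6 of 72 double-positive-like cells (8.33%), immature cells led by Rag1 and Rag2. Trav1 was among the markers that named the type 17-like and type 1-like clusters, so these shares are in part set by the naming. The median depths of these classes were 17386, 8145 and 2854.5 UMIs. Type 17-like cells were 0 of 25 WT cells and 24 of 296 KO cells, of which 22 were from hashtag 4 (0% and 4.78% ± 6.86, exact p = 0.4). By edgeR no gene was called (0 of 2158, 41 at an unadjusted p under 0.05), DESeq2 called 3, and 1 was called without WT hashtag 3. Sec62 was at 1.91 ± 0.34 (adjusted p = 0.258). Thymic MAIT stage 1 genes rose (12 genes, median 0.27, adjusted p = 1.19e-05, adjusted p = 0.545 with an estimated correlation), as did T cell receptor response genes by camera, though their median was -0.13 (adjusted p = 0.00746, adjusted p = 0.545 with an estimated correlation). The other 9 lists did not pass.

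The WT thymus library enriched with the tetramer held 53 kept cells, with no group to compare. Of its 709 barcodes 656 held under 100 UMIs, and it is not known whether the matrix is complete, so the shares describe these 53 cells alone. The kept cells fell into 29 stage 1-like cells (54.7%, interval 40.5 to 68.4%), led by Itm2a, Lef1, Ccr9 and Tnfrsf9, and 24 type 17-like cells (45.3%, 31.6 to 59.6%), led by Lgals3, S100a4, S100a6, Blk and Serpinb1a. Itm2a and Lef1 are genes of immature thymocytes and Blk of type 17 innate-like T cells. Of 39 cells with an alpha chain, 26 (66.7%, 49.8 to 80.9%) carried TRAV1 with TRAJ33, the MAIT alpha chain. These were 16 of 16 type 17-like cells (lower bound 79.4%) and 10 of 23 stage 1-like cells (43.5%, 23.2 to 65.5%), at median depths of 14607 and 5458 UMIs.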

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

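All tests of explanations in this part were chosen after the result was seen. A signal in data outside the comparisons was Xist, the RNA of the inactive X chromosome, with 269 UMIs in the WT thymus library enriched with the tetramer, where 48 of 53 cells held it and the Y-linked genes held 0. The thymus pool held 0 Xist UMIs, 144 Ddx3y UMIs and 223 Eif2s3y UMIs. The TCR library of the thymus pool, which carries no hashtag and entered no comparison, held MAIT evidence on the alpha chain in 60 cells (19.5%, interval 15.3 to 24.4%).

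Leaving out receptor segments, hemoglobin and hepatocyte genes, those with a small p (under 0.01) between KO and WT in T cells lay on chromosome 7, which carries the Sult2a genes, more often than its share of genes, with Isoc2a, Lrrk1, Gramd1a, Snrpn and Emp3 among them. They were 2.46% of tested genes at 0 to 40 Mb, the part with the deletion, 5.84% at 40 to 80 Mb and 0.251% beyond (Fisher p = 0.000495 for the first 80 Mb against the rest, and 0.00268 for chromosome 7 against other chromosomes), a course also seen over all cells (2.99%, 5.95% and 1.73%) and in iNKT-like (2.27%, 5.31% and 0.612%), CD8 (2.46%, 2.78% and 0.658%), NK-like (2.38%, 2.53% and 0.408%) and monocyte-like cells (1.12%, 4.71% and 0.733%), but not in B-like cells (2.65%, 1.06% and 1.41%). These sums come from the same libraries. The iNKT-like and CD8 cells are part of the T cells, and the T cells part of all cells, so the sums are no independent repeats. Loss of regulatory DNA next to the deletion is argued against for 14 of the 16 genes, which lay over 10 Mb away. The ratio to the share of genes was 2.20, as high on chromosome 7 in 1 of 10 splits, with 1.17 as the highest other, and 10 splits are too few for a share under 0.05. In the real split chromosome 6 had 2.41, and in 7 of the 9 other splits some chromosome was above 2.20. The highest, 4.41, rested on 3 genes of chromosome 18, and a highest value over all chromosomes is a higher bar than chromosome 7 alone. Since other splits also grouped genes by chromosome, the Fisher tests, which take genes as independent, cannot decide. They leave open both DNA of another strain linked to the deletion and an effect of the enzymes through bile acids.

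A split of WT replicates 1 and 3 with KO replicate 3 against the other libraries called more genes than KO against WT, which points to a structure of the samples. Klra8, an NK receptor gene of some mouse strains, held 139, 0 and 253 UMIs in NK-like cells of WT replicates 1, 2 and 3 and 0, 0 and 109 in those of KO replicates 1, 2 and 3. Pairs of neighbouring genes with a small p in T cells numbered 68 in that split (random draws: mean 31.8, highest 57), 20 in the real split (highest 19) and 25 in the split of WT replicate 1 with KO replicates 1 and 3 (highest 14). In B-like cells that first split gave 7 pairs, which 130 of 1000 draws also reached. It had 66 genes with a small p there against 188 in T cells. In T cells Klrb1c was at 63.92, 4.52 and 79.47 CPM in WT replicates 1, 2 and 3 and 5.21, 4.26 and 92.27 CPM in KO. Ifi213 was at 54.26, 3.61 and 39.15 CPM in WT and 3.36, 2.61 and 61.62 CPM in KO. Rnpep ran the same way, at 26.04, 5.72 and 18.08 CPM in WT and 3.59, 3.3 and 23.89 CPM in KO. Ifi202b, Ifi211, Ctse and Glo1 ran the opposite way. Mlycd, at 62.74, 50.14 and 67.9 CPM in WT and 24.18, 22.93 and 44.16 CPM in KO, followed that split within each genotype only. Apobec3 and Isoc2a, among others, did not follow it. Segments of another strain shared by those libraries thus stay open, and no biological explanation was tested. A different mixture of cell classes is argued against as the whole cause, since the split called 17 genes within conventional CD8 T-like cells.

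Hemoglobin genes fell in KO NK-like cells. Free hemoglobin RNA is argued against for most of the UMIs, as 98.6% of them lay in 10 of 714 cells, 8 of them WT and 2 KO. In the other NK-like cells hemoglobin was at 34.3, 140 and 123 CPM in WT replicates 1, 2 and 3. In KO it was at 22.9, 4.56 and 58.2 CPM, and free RNA stays open for these cells. Without cells of 50 or more hemoglobin UMIs Hbb-bs went from log2 -3.60 ± 0.63 to -1.81 ± 0.53 (edgeR adjusted p = 0.922) and Hba-a1 from -3.23 ± 0.65 to -2.42 ± 0.54 (edgeR adjusted p = 0.468). Since those cells were chosen by hemoglobin, a smaller fold was set beforehand, and red cells in the same droplet as an NK cell stay open. Fewer red cells in the KO fractions stay open too, with 3 libraries per group (exact p = 0.2).

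For counts of called genes, 10 splits of 6 samples are too few for a share under 0.05. Splits with at least as many calls as the real one, real count and highest other were 4, 1 and 12 over all cells, 10, 0 and 20 in T cells, 6, 1 and 2 in B-like, 10, 0 and 4 in ILC1-like, 2, 3 and 13 in NK-like, 7, 1 and 11 in cluster 13, 5, 1 and 9 in cluster 3, 10, 0 and 10 in CD4, 10, 0 and 17 in CD8, 5, 1 and 14 in iNKT-like, 10, 0 and 12 in monocyte-like, 10, 0 and 1 in neutrophil-like, 10, 0 and 7 in pDC-like, 10, 0 and 10 in regulatory T-like cells, and 10, 0 and 0 in the thymus pool. For gene lists they were 3, 11 and 15 over all cells, 4, 11 and 16 in T cells, 1, 5 and 4 in B-like, 5, 2 and 3 in ILC1-like, 8, 2 and 4 in NK-like, 2, 6 and 6 in cluster 13, 6, 2 and 9 in cluster 3, 1, 7 and 4 in CD4, 10, 0 and 8 in CD8, 8, 3 and 5 in iNKT-like, 3, 7 and 11 in monocyte-like, 2, 4 and 5 in neutrophil-like, 4, 4 and 6 in pDC-like, 10, 1 and 9 in regulatory T-like cells, and 8, 2 and 6 in the thymus pool. Highest other counts several times the real count point to a structure of the samples.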

How the results depend on the processing

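Tests without the interferon-led clusters, without the hepatocyte, erythroid and platelet clusters, with the Klra8 split as a term, without cells of high hemoglobin and camera without each library were chosen after seeing the data. Among the main values, 207 alternatives gave the same call or a count within 1.5 times. Of the others, 70 were stronger, 24 weaker and 6 turned in direction. Among other values these numbers were 1769, 127, 274 and 22. The exact permutation tests, whose p cannot fall under 0.1, could pass under no setting, so their call was the same beforehand unless the direction turned. The Trav1 share difference, for example, went from 0.531 to 0.0257 percentage points without WT replicate 1, and neither passed. Genes called under neither setting also count as the same call. The number of same calls is thus no measure of how stable the values were. The cause of the changes was not tested, except that leaving out a library or a filter changes the samples or genes tested.

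Counts of called genes moved as follows. By DESeq2 there were 83 over all cells, 7 in T cells, 5 in B-like, 0 in NK-like, 0 in cluster 13, 2 in cluster 3, 11 in iNKT-like, 3 in monocyte-like and 14 in neutrophil-like cells and 3 in the thymus pool. Without the low-count filter there were 23 in T cells, 137 in B-like, 38 in ILC1-like, 36 in NK-like, 37 in cluster 13, 67 in cluster 3, 46 in CD4, 29 in CD8, 77 in iNKT-like, 145 in monocyte-like, 104 in neutrophil-like, 46 in pDC-like and 35 in regulatory T-like cells and 75 in the thymus pool. With doublets kept there were 0 over all cells, 2 in cluster 13 and 3 in pDC-like cells, at the lower cluster resolution 0 in B-like and 2 in iNKT-like cells, and with the stricter cell filter 1 in monocyte-like cells. Without the interferon-led clusters there were 6 in iNKT-like cells. With the Klra8 split as a term there were 2 over all cells, 2 in B-like, 6 in NK-like, 0 in cluster 3, 5 in iNKT-like, 9 in neutrophil-like and 3 in regulatory T-like cells, and without cells of high hemoglobin 0 in NK-like cells. Each 0 was by edgeR unless DESeq2 is named.

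The replicate numbers were not taken to pair the samples, since same-numbered libraries correlated at -0.0686, -0.0323 and -0.0423 over all cells and in no sum all above 0.1. In neutrophil-like cells, where the block gave 15 calls, they were at 0.032, 0.112 and 0.154, and 5 of the 6 other pairs were under 0, so a pairing there stays open. With the replicate block there were 0 calls over all cells, 0 in cluster 13, 0 in cluster 3, 8 in iNKT-like, 3 in monocyte-like, 15 in neutrophil-like, 1 in pDC-like and 3 in regulatory T-like cells. The block turned Trav11 to log2 -0.0661 over all cells and -0.0394 in T cells.

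Leaving out each library gave 0 to 6 calls over all cells, 1 to 4 in B-like, 0 to 6 in ILC1-like, 0 to 10 in NK-like, 0 to 17 in cluster 13, 0 to 5 in cluster 3, 0 to 4 in CD4, 0 to 2 in CD8, 0 to 13 in iNKT-like, 0 to 4 in monocyte-like, 0 to 8 in neutrophil-like, 0 to 4 in pDC-like, 0 to 1 in regulatory T-like cells and 0 to 1 in the thymus pool. The difference in Trav11 share ran from -0.833 to 0.863, in MAIT receptors from -0.0780 to 0.0440 and in clonotypes from -3.67 to 255.

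Sult2a8 passed only by DESeq2 (adjusted p = 1.41e-05). No liver list passed with an estimated correlation (0 lists, lowest adjusted p = 0.0876), and fry passed 1, while edgeR on cell counts passed 1 class. The Trav11 share difference was 0.123 with at least 2 UMIs, and the MAIT receptor difference 0.0694 on the alpha chain alone. Among the other values, Trav11 turned without the interferon-led clusters (log2 -0.0391 over all cells, -0.00798 in T cells) and Cxcl9 in monocyte-like cells with doublets kept (-0.0793).

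Leaving out each library also turned some other values. Adjusted p ran from 1.18e-15 to 0.992 for the cycling list over all cells (turned without KO replicate 2), from 0.000416 to 0.555 for the interferon list (KO replicate 1) and from 7.4e-07 to 0.794 for the mitochondrial list in neutrophil-like cells (WT replicate 1). Differences in share, KO minus WT, ran from -0.0102 to 1.77 for conventional CD8 T-like (KO replicate 1), from -4.73 to 1.86 for iNKT-like (KO replicate 2), from -0.0450 to 0.175 for MAIT or type 17 (WT replicate 1 and KO replicate 3), from -1.45 to 0.0574 for NK-like (WT replicate 3) and from -4.58 to 17.6 for thymic double-positive-like cells (WT hashtag 7 and KO hashtag 5). Trav11 ran from log2 -0.263 to 0.395 over all cells and from -0.219 to 0.395 in T cells, and turned without WT replicate 1 and KO replicates 1 and 3 in both and without WT replicate 3 over all cells. A test of Trav1 T cells by gene was not run, since WT replicate 1 held 3 such cells against a minimum of 10, nor one of thymus Trav1 cells, with 0 in WT hashtags 2 and 3 and KO hashtag 5.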

Other observations

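The MAIT alpha CDR3 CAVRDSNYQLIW, which pairs TRAV1 with TRAJ33, was shared by all liver libraries, with 1, 4 and 1 cells in WT replicates 1, 2 and 3 and 3, 2 and 3 cells in KO replicates 1, 2 and 3. The largest liver clonotype, in WT replicate 2, held 26 cells with TRB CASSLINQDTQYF and TRA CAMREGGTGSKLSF. Among tetramer-enriched thymocytes, TRBV13-3 was the beta segment in 13 of the cells with the MAIT alpha chain, and 16 of 51 cells in the TCR library (31.4%) held MAIT evidence on both chains.

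In the thymus pool, a Trav1 UMI was found in 19 of 47 cycling-like cells (40.4%) and in 4 of 38 stage 1-like cells (10.5%), whose median depths of 25785 and 4088 UMIs keep the shares from being compared. The liver libraries were male by their RNA, with 3 Xist UMIs in WT and 2 in KO against 2143 and 2229 Ddx3y UMIs.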
